A study of Homo sapiens with 7 samples.

How the data were processed

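RNA was measured by sequencing in 7 libraries of neurons induced from H1 cells, an established human embryonic stem cell line, per the labels. The groups differ in the transcription factors used: Ngn2 alone (2 libraries), a combination with Myt1l (called AM, 2 libraries) and a combination with Dlx2 (called AD, 3 libraries). Some items are not reported here. Per the labels, Ngn2 and AM neurons are glutamatergic and AD neurons GABAergic. The neurons grew with mouse glia, carried an EGFP label, and were sorted by flow cytometry 6 weeks after the transgenes were switched on. Total RNA was extracted with Trizol and libraries were made with NuGen and NEB reagents, per the labels' protocols.

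The deposited values are log2 values of TPM (transcript abundance scaled to the same total in each library) plus 1, made by the authors: taking 2 to the power of each value and subtracting 1 gave totals between 999999.4 and 1000000.5 in every library. The unit follows from those totals, since the analysis was planned for plain TPM and the table turned out to hold log2(TPM + 1); the planned test on log2(TPM + 1) was used without change. The submitters' processing notes name STAR, SAMtools and the hg38 build. The tool that made TPM, its gene annotation and any filter are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval is given. One AM column carries a number that matches no AM sample title, so that library was used as an AM library without a number.

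The table holds 26761 gene symbols, of which 8684 are at 0 in all 7 libraries. Genes with at least 1 TPM in at least 2 libraries were kept, 14908 in all. An exact 0 can be a failed estimate here: GRIN1 and HLA-E are listed at 0 in 7 of 7 libraries. Where a group has a library at 0, values are therefore given for each library, without a mean or a fold. Symbols were matched to GENCODE v29 (GRCh38, the same assembly as hg38): 24002 matched directly, 25 through an older symbol and 2734 matched no single gene. Coordinates are from that annotation, counted from 1.

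Values were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a pseudocount of 1, so changes of low genes are understated. One fit held all 7 libraries with a mean per group, which left 4 residual degrees of freedom, and moderated variances with a trend added 4.32 prior degrees of freedom. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the kept genes, with a threshold of 0.05. The comparisons were AD with the mean of Ngn2 and AM, AD with Ngn2, AD with AM, and AM with Ngn2. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

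A total of 29 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the first set of alternatives. The lists cover reprogramming factors, neuroligins and neurexins, GABAergic identity, glutamatergic identity, ionotropic glutamate receptors, GABA and glycine receptors, excitatory and inhibitory postsynaptic scaffolds, other synaptic adhesion molecules, presynaptic release machinery, voltage-gated channels, interneuron peptides and calcium binding proteins, peripheral and sensory neuron markers, cholinergic and monoaminergic markers, forebrain patterning, HOX genes, pluripotency, cell cycle, neural progenitor, astrocyte, oligodendrocyte lineage and microglia, mesenchymal and fibroblast, skeletal muscle, epithelial and endothelial, immediate early and stress, mitochondrially encoded, cholesterol synthesis, neuronal maturation, and MHC class I and interferon genes. Of these, 28 had at least 3 kept genes. The mitochondrially encoded list had 0 genes under its symbols among those analysed here and gave no result. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data.

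The rule for named genes took the reprogramming factors, the neuroligins and neurexins, SLC17A6, SLC17A7, GAD1, GAD2 and SLC32A1 in every comparison. To these were added the 8 genes with the largest change in each direction that passed the test, reached a mean of 5 TPM in the higher group and had no overlap between libraries. Up to 4 members of each list described were also named, by smallest p where any passed and otherwise by largest change. Y-linked genes and XIST were left out. DLX5 and MEIS2 in the first comparison, CALCA in AD against AM, and SNORA109, MALAT1, GAPDH, CLU, GFAP, APOE, GJA1, GRIN1 and HLA-E fall outside that rule and were named after their values were seen.

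The fit was tested on simulated data with the real genes' means and moderated variances, with 50 genes changed at each size in each comparison. The changed genes were drawn only from genes above a minimum mean level, with normal noise, so the rates do not cover low genes or failed estimates. Each gene had the same variance in every group, as the fit assumes, so the rates do not cover a spread that differs between groups or libraries. In AD against the mean of Ngn2 and AM, the test called 14%, 60%, 94% and 92% of genes changed by 1, 2, 4 and 6 on the log2 scale. The same sizes gave 6%, 40%, 86% and 92% in AD against Ngn2, 8%, 52%, 88% and 82% in AD against AM, and 2%, 28%, 76% and 86% in AM against Ngn2. Calls among unchanged simulated genes numbered 7, 7, 9 and 7 in that order.

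Alternatives fixed before the data were examined were other pseudocounts and filters, quantile normalization, median centring, a robust variance prior, only the compared groups, a block on replicate number, and leaving out each library. Alternatives chosen after seeing the data were a GC correction, a block in which the unnumbered AM library takes the number 3, a term for the libraries with SNORA109 above 0, removal of 4 abundant RNAs, and library quality weights. Only AD has libraries on both sides of the SNORA109 split, so that term is estimated from AD 3 against AD 1 and AD 2 alone. Figures were drawn with matplotlib.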

Results

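The data are transcript levels of 7 libraries: 2 of Ngn2 neurons, 2 of AM neurons and 3 of AD neurons, all induced from human embryonic stem cells by transcription factors. The series title concerns neuroligin-4 at excitatory synapses, and the design sets the 2 glutamatergic kinds beside the GABAergic kind. Depth per library is unknown because TPM values do not keep it. Genes above 0 numbered 10723, 12335 and 13692 in AD libraries 1, 2 and 3, 13668 in AM library 1, 13188 in the unnumbered AM library, and 15887 and 14711 in Ngn2 libraries 1 and 2.

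Libraries of a group were closest to each other. Across kept genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.914 between the Ngn2 libraries, 0.862 between the AM libraries and 0.825 to 0.863 among the AD libraries. Between groups it was 0.771 to 0.825 for AD with AM, 0.791 to 0.832 for AD with Ngn2, and 0.786 to 0.796 for AM with Ngn2. The libraries also split in a way that crosses the groups: SNORA109, a small nucleolar RNA, stood at 13076 TPM in AD 3, 12702 in AM 1 and 18997 in the unnumbered AM library and was listed at 0 in the other 4. Library deviation also tracked transcript GC content across genes, with Spearman's rho from -0.276 in AD 1 to 0.297 in Ngn2 1.

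**Figure D1:**
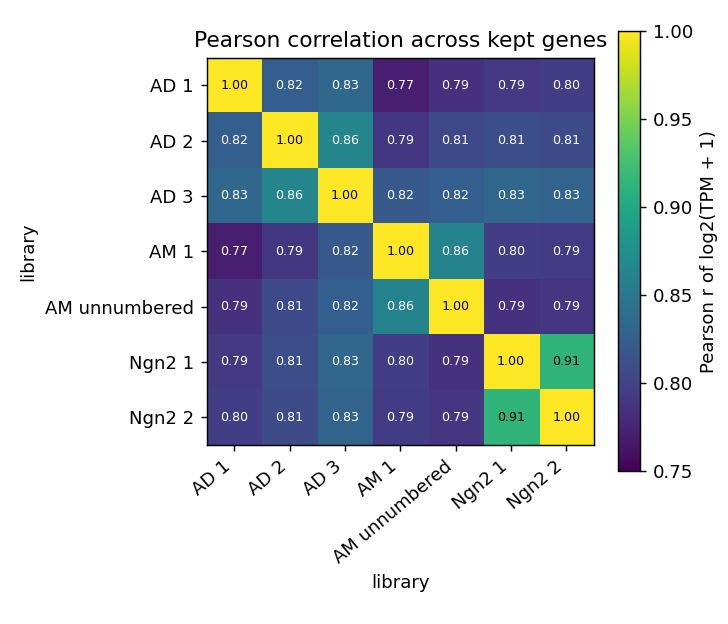
Pearson correlation of log2(TPM + 1) across kept genes for each pair of the 7 libraries, both axes listing libraries and colour giving r. The Ngn2 pair is at 0.914 and the AM pair at 0.862, above the range of 0.771 to 0.832 seen between groups. The AD pairs are at 0.825 to 0.863, so the lowest of them lies inside that range.

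Genes of the introduced factors were examined first. NEUROG2 was listed at 0 in 7 of 7 libraries. DLX2 (chromosome 2, 172099439 to 172102900) was 21.6 ± 2.85 TPM in AD (SD, n = 3) and 3.58 ± 0.134 in AM (SD, n = 2), and was listed at 0 and 0 in Ngn2. MYT1L was 61.6 ± 18.0 TPM in AD, 54.1 ± 8.29 in AM and 84.8 ± 5.88 in Ngn2. DLX2 rose in AD against Ngn2 (limma with Benjamini-Hochberg adjusted p = 0.0305; no fold is given against a group listed at 0), and was the 1 of 3 tested members that passed in any comparison. Adjusted over the list alone, 1, 1, 1 and 2 members were higher and 0, 0, 1 and 0 lower in the comparisons in the order listed in the processing. The table does not separate transgene from endogenous transcripts.

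Neuroligins, postsynaptic adhesion proteins, and neurexins, their presynaptic partners, did not pass the test in any of the 4 comparisons (0 of 7 members by limma with Benjamini-Hochberg adjustment). NLGN4X (chromosome X, 5840637 to 6228863, protein coding) was 41.9 ± 12.7 TPM in AD (SD, n = 3), 14.8 ± 12.5 in AM (SD, n = 2) and 29.1 ± 10.02 in Ngn2 (SD, n = 2). NLGN1 (chromosome 3, 173396284 to 174286644) was 149.6 ± 52.9 TPM in AD, 50.6 ± 13.6 in AM and 62.3 ± 6.75 in Ngn2. Against the mean of Ngn2 and AM, its log2 change in AD was 1.36 (SE 0.30, limma with Benjamini-Hochberg adjusted p = 0.0842). Its AD libraries did not overlap the others. In the simulation, 14% of genes changed by 1 were called in that comparison, so a gene that did not pass cannot be taken as unchanged. NLGN2 was 15.4 ± 5.74, 15.2 ± 13.4 and 43.6 ± 11.8 TPM, and NLGN3 30.2 ± 24.1, 7.77 ± 6.10 and 45.6 ± 16.8 TPM, in AD, AM and Ngn2. NRXN2 was 4.45 ± 0.930, 3.43 ± 1.63 and 5.76 ± 3.50 TPM, and NRXN3 29.1 ± 6.80, 22.3 ± 6.39 and 8.27 ± 2.40, in the same order. Adjusted over the list alone, 1 member was higher in AD than in the mean of Ngn2 and AM, 2 in AD than in Ngn2, 1 in AD than in AM and 0 in AM than in Ngn2. As a list, they had an adjusted p of 0.0681, 0.156, 0.0718 and 0.649 by limma's camera. At an unadjusted p under 0.05, 2539, 2489, 2460 and 2807 of all 14908 genes passed in these comparisons.

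**Figure D2:**
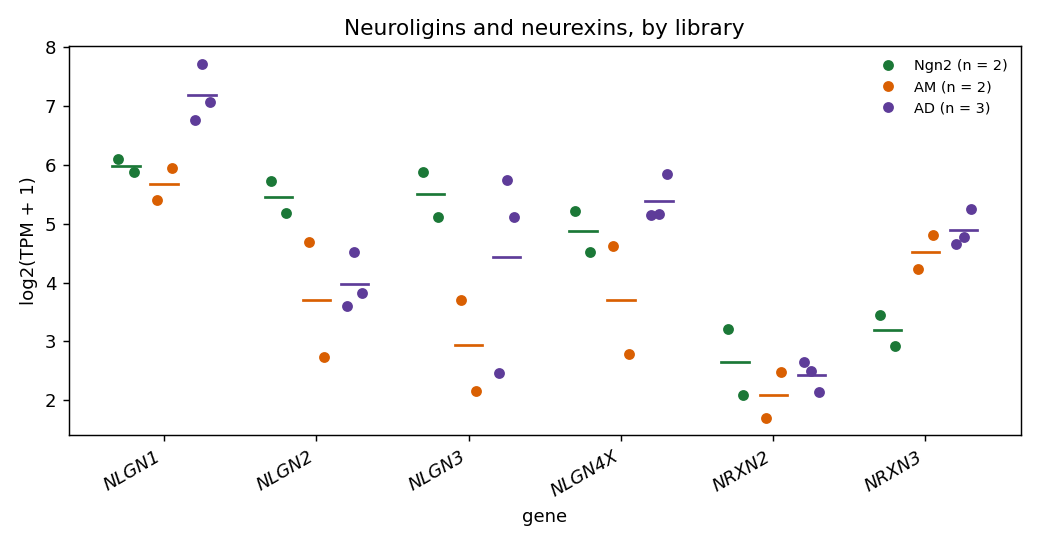
Levels of 2 neurexins and 4 neuroligins in log2(TPM + 1) for each library, with points for libraries and short lines for group means (Ngn2 n = 2, AM n = 2, AD n = 3). NLGN4X lies at 34.2 to 56.6 TPM in AD, 5.91 to 23.6 in AM and 22.0 to 36.2 in Ngn2.

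AD neurons were compared with the mean of Ngn2 and AM, the GABAergic kind against the 2 glutamatergic kinds. GAD1, which makes GABA from glutamate (chromosome 2, 170813213 to 170861151), was 471 ± 53.1 TPM in AD (SD, n = 3), 50.6 ± 3.51 in AM (SD, n = 2) and 0.865 ± 0.417 in Ngn2 (SD, n = 2). It rose by 5.59 on the log2 scale (SE 0.28, limma with Benjamini-Hochberg adjusted p = 1.7e-04). The homeobox gene DLX1 stood at 917, 949 and 1098 TPM in AD, 160 and 269 in AM, and 0 and 0.950 in Ngn2. SST, the interneuron peptide somatostatin (chromosome 3, 187668906 to 187670399), was 1729 ± 364 TPM in AD, 140.1 ± 62.9 in AM and 19.3 ± 23.0 in Ngn2. SPARC, a matricellular protein, fell, from 363 ± 10.7 TPM in AM and 79.3 ± 13.1 in Ngn2 to 0, 0 and 1.70 in AD.

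Of 17 tested GABAergic identity genes, 7 rose, 0 fell and 10 did not pass: GAD1, GAD2, DLX1, DLX5, DLX6, DLX6-AS1 and MEIS2 (adjusted over the list alone, 10 higher and 2 lower). The list was higher by limma's camera, adjusted p = 1.3e-12, and lost the call at adjusted p = 0.256 with an estimated correlation. GAD2, the other GABA-synthesizing enzyme, stood at 73.5, 64.9 and 72.8 TPM in AD, 11.2 and 58.0 in AM, and 0 and 0.360 in Ngn2. MEIS2 was 163 ± 20.5 TPM in AD against 449 ± 23.8 in AM and 2.66 ± 0.735 in Ngn2, so it was called against the mean of the log2 values while lying below AM. DLX6 stood at 277, 330 and 210 TPM in AD and 137 and 533 in AM, and DLX5 at 56.0, 70.9 and 128 in AD and 56.6 and 44.4 in AM, so both overlapped AM, and both were listed at 0 in Ngn2. SLC32A1, the vesicular GABA transporter, did not pass (3.51, 27.3 and 44.0 TPM in AD, 0.650 and 8.45 in AM, 0 and 0 in Ngn2). Of 17 glutamatergic identity genes, 0 passed (adjusted over the list alone, 0 higher and 3 lower; camera adjusted p = 0.245), and SLC17A6, a vesicular glutamate transporter, had a log2 change of -2.51 (SE 0.50, adjusted p = 0.0700). Its AD levels (6.64, 13.1 and 26.6 TPM) overlapped AM (33.6 and 14.6; adjusted p = 0.621 against AM), with Ngn2 at 264 and 319. DLX6-AS1 overlaps DLX6 on the other strand, and strand use in the counting is not given, so their reads may not be separable.

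Receptor lists moved in the same comparison. Ionotropic glutamate receptors, 1 of 15 higher and 0 lower (adjusted over the list alone, 4 and 0), had a camera adjusted p of 0.0107, and adjusted p = 0.357 with an estimated correlation. The AMPA receptor subunit GRIA1 was the member that rose, at 128 ± 9.19 TPM in AD, 39.6 ± 3.42 in AM and 47.5 ± 10.4 in Ngn2. GABA and glycine receptors, 1 of 17 higher (adjusted over the list alone, 4 and 0), had adjusted p = 0.0269, and adjusted p = 0.483 with an estimated correlation. GABRA4 rose, at 32.4, 27.8 and 22.2 TPM in AD, 1.28 and 2.48 in AM, and 0 and 0 in Ngn2. HOX genes, which mark hindbrain and spinal positions, had 0 of 8 members called (adjusted over the list alone, 0 higher and 4 lower). The list was lower at camera adjusted p = 7.9e-04, and adjusted p = 0.483 with an estimated correlation. Only 8 of its 24 genes were kept. Against AM alone the HOX list did not pass by limma's camera (median log2 change -0.36, adjusted p = 0.303). Its median against Ngn2 alone was -2.11, so the call does not show AD below AM.

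Among interneuron genes, 3 of 14 rose and 0 fell (adjusted over the list alone, 5 higher and 2 lower): SST, the calcium binding protein CALB1 and the tachykinin TAC3. CALB1 was 235 ± 37.1 TPM in AD, 12.6 ± 13.2 in AM and 42.8 ± 3.85 in Ngn2, and TAC3 stood at 99.3, 172 and 137 TPM in AD, 0 and 0 in AM, and 12.4 and 17.8 in Ngn2. Among peripheral and sensory markers, 0 rose and 4 of 14 fell (adjusted over the list alone, 3 higher and 6 lower). They included the transcription factors POU4F1 and POU4F2. POU4F2 was listed at 0 in each AD library and stood at 26.1 and 46.9 TPM in AM and 68.9 and 20.3 in Ngn2. Presynaptic genes had 2 of 32 higher (adjusted over the list alone, 3 higher and 1 lower): the vesicle calcium sensor SYT1, and SYT4. SYT1 was 625 ± 132 TPM in AD, 238 ± 23.2 in AM and 294 ± 34.7 in Ngn2. SYT4 was 899 ± 107 TPM in AD, 221 ± 38.7 in AM and 686 ± 7.62 in Ngn2.

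In all, 79 genes rose and 40 fell in AD against the mean of Ngn2 and AM, of 14908 tested by limma with Benjamini-Hochberg adjustment. The genes with the largest rises also included SERTM1 (197 ± 26.6 TPM in AD, 2.18 ± 0.523 in AM, 0.180 and 1.24 in the Ngn2 libraries), the corticotropin-releasing hormone binding protein CRHBP (376, 192 and 54.6 TPM in AD) and LINC01305 (45.4, 53.1 and 34.5 TPM in AD, listed at 0 in the other 4). Those with the largest falls included MIR217HG, NDUFA3, SERPINF1, INHBE and ASNA1. NDUFA3, a respiratory chain subunit that every cell uses, is listed at 0, 0 and 0 in AD, so such falls cannot be told from failed estimates. Median centring gave 78.5% of calls higher against 66.4% without it, where the median change of all genes was -0.15 on the log2 scale. Without AD 1, AD 2, AD 3, AM 1, the unnumbered AM library, Ngn2 1 or Ngn2 2 in turn, the higher and lower counts were 52 and 18, 10 and 6, 17 and 15, 20 and 3, 23 and 4, 28 and 6, and 31 and 7. A term for the libraries with SNORA109 above 0 left 29 higher and 13 lower.

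Against Ngn2 alone, AD neurons differed in genes of GABA synthesis and of vesicular glutamate transport. GAD1 rose by 7.996 on the log2 scale (SE 0.33, limma with Benjamini-Hochberg adjusted p = 2.7e-05). SLC17A6, a vesicular glutamate transporter (chromosome 11, 22338097 to 22379503), fell by 4.34 (SE 0.60, adjusted p = 0.0162), from 292 ± 39.2 TPM in Ngn2 (SD, n = 2) to 15.5 ± 10.2 in AD (SD, n = 3). SLC17A7, another such transporter (chromosome 19, 49429401 to 49442360), stood at 32.3 and 39.8 TPM in Ngn2 and was listed at 0 in each AD library.

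Of the GABAergic list, 9 of 17 rose, 0 fell and 8 did not pass (adjusted over the list alone, 10 higher and 1 lower), with camera adjusted p = 1.9e-18, and adjusted p = 0.130 with an estimated correlation. Of 17 glutamatergic identity genes, 0 rose and 3 fell (SLC17A6, SLC17A7 and NHLH1), and the list did not pass (adjusted p = 0.168; adjusted over the list alone, 1 higher and 5 lower). HOX genes had 2 of 8 lower (HOXA2 and HOXD8; adjusted over the list alone, 0 and 5), adjusted p = 5.1e-05, and adjusted p = 0.244 with an estimated correlation. HOXD8 stood at 0, 0 and 0 TPM in AD and 30.8 and 43.0 in Ngn2. Epithelial and endothelial genes had 1 of 5 higher (adjusted over the list alone, 2 and 0), adjusted p = 4.4e-04, and adjusted p = 0.241 with an estimated correlation. That gene was EPCAM, an epithelial adhesion protein, at 446 ± 69.3 TPM in AD, 477 ± 155 in AM and 28.4 ± 25.0 in Ngn2.

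Neuronal maturation genes had 2 of 20 lower and 0 higher (adjusted over the list alone, 0 and 3), adjusted p = 0.00172, and adjusted p = 0.241 with an estimated correlation. NEFL, the light neurofilament chain (chromosome 8, 24950955 to 24957110), fell by 2.28 (SE 0.20, limma with Benjamini-Hochberg adjusted p = 0.00175), and ELAVL4, a neuronal RNA binding protein, by 1.88 (SE 0.32). The nuclear RNA MALAT1 stood at 42675, 39371 and 23042 TPM in AD and 11015 and 13239 in Ngn2, and the glycolytic gene GAPDH at 152, 135 and 234 in AD and 1035 and 716 in Ngn2. Of the kept genes, 28.9%, 19.1% and 11.8% were at 0 in AD and 4.57% and 8.02% in Ngn2. Cholesterol synthesis had 0 of 21 called (adjusted over the list alone, 0 and 0) while the list was lower at adjusted p = 0.00927, and adjusted p = 0.241 with an estimated correlation. Astrocyte markers had 2 of 8 lower (SPARC and ALDOC; adjusted over the list alone, 0 and 2), adjusted p = 0.026, and adjusted p = 0.342 with an estimated correlation. Among abundant astrocyte genes, CLU reached at most 15.5 TPM, GFAP and APOE stood at 1.94 and 2.09 TPM in Ngn2 2 and were listed at 0 in the other libraries, and GJA1 was listed at 0 in all 7. SPARC, also on the astrocyte list, was not low: it stood at 88.6 and 70.0 TPM in Ngn2 and 370 and 355 in AM. A 0 can be a failed estimate, and the glia were mouse while the build was human. These values therefore do not show that astrocyte RNA was absent.

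In all, 143 genes rose and 90 fell in AD against Ngn2. Further large rises were TPBG, an oncofetal glycoprotein (213 ± 54.7 TPM in AD, 1.04 ± 0.0212 in Ngn2), DLX5 and DLX6. CTXN3, LHX9, PVALB and CDC37L1-AS1 were listed at 0 in every AD and AM library, and stood at 76.5 and 108, 96.0 and 65.6, 35.3 and 52.3, and 51.8 and 47.2 TPM in Ngn2. NRN1 and SIM1 also fell. The share of calls that were higher was 61.4%, and 78.9% after median centring, where the median of all genes was -0.25 without it. Leaving out AD 1, AD 2, AD 3, AM 1, the unnumbered AM library, Ngn2 1 or Ngn2 2 gave 119 and 51, 47 and 19, 50 and 22, 79 and 40, 75 and 34, 46 and 1, and 48 and 3 higher and lower genes. With the SNORA109 term, 50 were higher and 20 lower.

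Against AM alone, AD neurons differed in both directions. GAD1 rose by 3.19 (SE 0.33, limma with Benjamini-Hochberg adjusted p = 0.00977), DLX1 by 2.24 and DLX6-AS1 by 2.50, while MEIS2 fell by 1.46. Of the GABAergic list, 3 of 17 rose and 1 fell (adjusted over the list alone, 4 and 2), and the list did not pass (adjusted p = 0.0641). CGA, the common alpha subunit of glycoprotein hormones (chromosome 6, 87085498 to 87095406), stood at 16.7, 0 and 17.3 TPM in AD and 1027 and 1066 in AM. TPH1, an enzyme of serotonin synthesis, stood at 92.5 and 145 TPM in AM and was listed at 0 in each AD library.

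Ionotropic glutamate receptors had 2 of 15 higher, GRIA1 and the kainate subunit GRIK1 (adjusted over the list alone, 2 and 0), with adjusted p = 0.0335, and adjusted p = 0.675 with an estimated correlation. GABA and glycine receptors had 1 of 17 higher (adjusted over the list alone, 4 and 0), with adjusted p = 0.0335, and adjusted p = 0.675 with an estimated correlation. Presynaptic genes had 3 of 32 higher, SYT1, SYT4 and the active zone protein ERC2 (adjusted over the list alone, 3 and 0). Adhesion molecules had 3 of 34 higher, FLRT2, TENM2 and CNTNAP2 (adjusted over the list alone, 3 and 1), and FLRT2 stood at 114, 200 and 114 TPM in AD and 8.04 and 16.4 in AM. Among 14 sensory markers, 1 rose (NTRK2) and 4 fell, POU4F1, POU4F2 and CALCA among them (adjusted over the list alone, 4 and 6).

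In all, 130 genes rose and 166 fell in AD against AM. TAC3, SERTM1, CRHBP, SEMA3E, MAP7D2 and UBE2L6 were among the largest rises, and SPARC, CRYBA2, USH1C and SERPINF1 among the largest falls. CRYBA2 stood at 358 and 125 TPM in AM and USH1C at 192 and 87.9. Counts depended on single libraries: without AD 1, AD 2, AD 3, AM 1, the unnumbered AM library, Ngn2 1 or Ngn2 2, they were 38 and 45, 7 and 16, 12 and 23, 3 and 0, 3 and 0, 16 and 13, and 22 and 17. Where limma called 0 lower, without AM 1 and without the unnumbered AM library, 1776 and 1994 genes had an unadjusted p under 0.05. With the SNORA109 term limma called 0 higher and 0 lower, with 1612 genes at an unadjusted p under 0.05.

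The 2 glutamatergic kinds were then compared with each other. In AM, SLC17A6 fell by 3.65 against Ngn2 (SE 0.66, limma with Benjamini-Hochberg adjusted p = 0.0288), to 24.1 ± 13.5 TPM (SD, n = 2). SLC17A8, another vesicular glutamate transporter (chromosome 12, 100357079 to 100422059), rose by 4.52 (SE 0.92, adjusted p = 0.0424), to 72.4 ± 30.8 TPM against 2.15 ± 1.13. SLC17A7 stood at 1.66 and 0 TPM in AM and fell. GAD1 rose by 4.81 (SE 0.36, adjusted p = 0.00173), and MEIS2 by 6.95 (SE 0.32, adjusted p = 1.8e-04).

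Of the GABAergic list, 7 of 17 rose in AM and 0 fell (adjusted over the list alone, 10 and 0), with adjusted p = 6.6e-13, and adjusted p = 0.123 with an estimated correlation. The glutamatergic list had 1 higher and 2 lower of 17 (adjusted over the list alone, 2 and 6) and did not pass (adjusted p = 0.461). Neuronal maturation genes had 0 higher and 4 lower of 20: NEFL, NEFM, STMN2 and GAP43 (adjusted over the list alone, 0 and 6). That list had adjusted p = 7.3e-06, and adjusted p = 0.123 with an estimated correlation. NEFL was 474 ± 72.5 TPM in AM and 2846 ± 248 in Ngn2. STMN2, a microtubule regulator, was 1722 ± 98.1 TPM in AM and 3755 ± 684 in Ngn2. MALAT1 stood at 29350 and 38362 TPM in AM and 11015 and 13239 in Ngn2, GAPDH at 563 and 372 against 1035 and 716, and 12.7% and 15.2% of kept genes were at 0 in AM against 4.57% and 8.02% in Ngn2.

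Epithelial genes had 1 of 5 higher, EPCAM (adjusted over the list alone, 4 and 0), with adjusted p = 6.3e-05, and adjusted p = 0.186 with an estimated correlation. HOX genes had 1 of 8 lower, HOXA2 (adjusted over the list alone, 0 and 5), with adjusted p = 0.0355, and adjusted p = 0.746 with an estimated correlation. Cholesterol synthesis had 0 of 21 called (adjusted over the list alone, 0 and 0) with the list lower at adjusted p = 0.0358, and adjusted p = 0.366 with an estimated correlation. Monoaminergic genes had 3 of 11 higher and 1 lower (adjusted over the list alone, 3 and 3): TPH1, the decarboxylase DDC and the vesicular transporter SLC18A1 rose, and the choline transporter SLC5A7 fell. DDC was not particular to AM: it stood at 218, 467 and 391 TPM in AD, 108 and 169 in AM, and 4.95 and 28.6 in Ngn2. In AD against Ngn2, 2 of 11 rose and 0 fell (adjusted over the list alone, 3 and 4). These were DDC (limma with Benjamini-Hochberg adjusted p = 0.0159) and SLC18A2 (adjusted p = 0.0286). SLC18A1 stood at 74.0 and 191 TPM in AM and 0.860 and 5.88 in Ngn2. Among channels, SCN2A fell to 74.3 ± 0.226 TPM from 258 ± 16.8, and CACNA2D1 rose to 341 ± 1.60 from 127 ± 7.05 (of 28, 1 and 1; adjusted over the list alone, 2 and 2).

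In all, 251 genes rose and 165 fell in AM against Ngn2. The largest rises included CGA, HEPACAM2 (1124 and 1121 TPM in AM, 0 and 4.96 in Ngn2), the peptide gene CALCA (383 and 347 against 0 and 0), RASSF6 (351 and 318 against 0 and 0), CRYBA2 and ANKRD34B. The largest falls included UBE2L6, HCG27, TMEM74B and TMEFF1. The share of calls that were higher was 60.3%, and 76.8% after median centring, where the median of all genes was -0.23 without it. Without AD 1, AD 2, AD 3, AM 1, the unnumbered AM library, Ngn2 1 or Ngn2 2, counts were 288 and 187, 184 and 103, 192 and 97, 34 and 21, 10 and 7, 60 and 5, and 59 and 3. With the SNORA109 term, 6 were higher and 1 lower, and AM and Ngn2 lie wholly on opposite sides of that split. The term is estimated from AD 3 against AD 1 and AD 2 alone, so this fall does not show that the split made the calls.

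**Figure D3:**
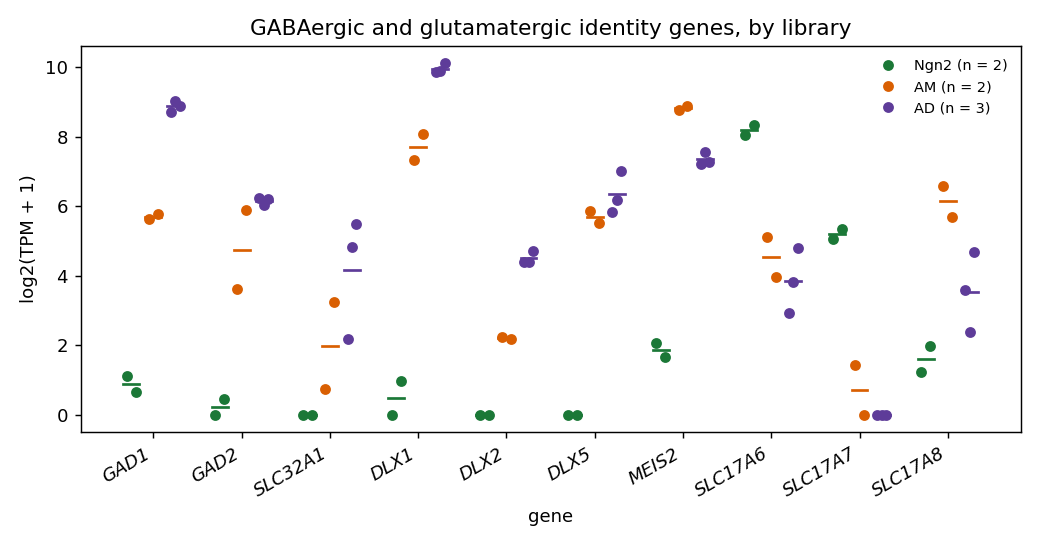
Levels of 10 identity genes in log2(TPM + 1) for each library, with points for libraries and short lines for group means (Ngn2 n = 2, AM n = 2, AD n = 3). GAD1 is at 418 to 524 TPM in AD and 48.1 to 53.1 in AM, and SLC17A6 at 264 and 319 in Ngn2.

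The remaining lists did not pass in any comparison, and are given for AD against the mean of Ngn2 and AM as the median log2 change and camera adjusted p. Adjusted over the list alone, 0 members were higher and 0 lower where no other count is given here, by limma with Benjamini-Hochberg adjustment, and 2539 of all kept genes had an unadjusted p under 0.05. Excitatory postsynaptic scaffold genes had 0 of 21 called (0.32, adjusted p = 0.139). Inhibitory scaffold genes had 0 of 8 called, with a median of -0.37 and a mean of -0.22 beside a test direction of higher (adjusted p = 0.991). Other adhesion molecules had FLRT2 higher and LRRTM2 lower of 34 (0.13, adjusted p = 0.139; adjusted over the list alone, 7 higher and 2 lower). The presynaptic list had a median of -0.04 and a mean of -0.18 beside a test direction of higher (adjusted p = 0.294; adjusted over the list alone, 3 higher and 1 lower). Voltage-gated channels had 0 of 28 called (0.02, adjusted p = 0.266), and interneuron genes gave 0.44 (adjusted p = 0.139; adjusted over the list alone, 5 higher and 2 lower). Sensory markers gave -1.59 (adjusted p = 0.139; adjusted over the list alone, 3 higher and 6 lower), monoaminergic genes -0.97 (SLC18A2 higher and TPH1 lower of 11, adjusted p = 0.772; adjusted over the list alone, 2 higher and 2 lower) and forebrain patterning -1.20 (0 of 7 called, adjusted p = 0.283; adjusted over the list alone, 0 higher and 1 lower). Pluripotency genes had 0 of 6 called (-0.70, adjusted p = 0.224). Cell cycle genes had 0 of 18 called, with a median of -0.03 and a mean of 0.11 beside a test direction of higher (adjusted p = 0.440). Neural progenitor genes had SOX1 higher of 11 (0.68, adjusted p = 0.294; adjusted over the list alone, 2 higher and 2 lower). Oligodendrocyte and microglia genes had 0 of 5 called (0.38, adjusted p = 0.25; adjusted over the list alone, 1 higher and 0 lower), and muscle genes 0 of 9 (-0.56, adjusted p = 0.409). Mesenchymal genes had 0 of 11 called, with a median of -0.24 and a mean of 0.10 beside a test direction of higher (adjusted p = 0.912). Immediate early and stress genes had 0 of 18 called (0.24, adjusted p = 0.285), and MHC class I and interferon genes 0 of 15 (-0.72, adjusted p = 0.881). Reprogramming factors had a median of -0.18 and a mean of 0.75 beside a test direction of higher (adjusted p = 0.365; adjusted over the list alone, 1 higher and 0 lower).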

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

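The GC correction, the block with the unnumbered AM library numbered 3, the SNORA109 term, the removal of 4 abundant RNAs and the library quality weights were chosen after seeing the data, and the cause of a moved count was not tested except where given. No result called in the report or under an alternative turned its direction. A change of sign between results that passed in neither was not counted. Of the named gene results under alternatives, 7048 stayed on their side of the threshold, 1220 lost the call and 53 gained it. Of the list results, 2269 stayed, 54 lost the call and 25 gained it. Counts of calls follow as higher and lower, in AD against the mean of Ngn2 and AM, AD against Ngn2, AD against AM, and AM against Ngn2, where the values of the report are 79 and 40, 143 and 90, 130 and 166, and 251 and 165. Only counts that moved by over 1.5 times are given. With a pseudocount of 0.1, lower counts became 21 in the first comparison, 217 in AD against Ngn2 and 265 in AM against Ngn2. With no filter on low values, counts were 45 and 12 in the first comparison and 66 and 84 in AD against AM. Quantile normalization gave 120 higher in the first comparison. Median centring gave 135 higher there, 265 higher in AD against Ngn2 and 108 lower in AM against Ngn2. With only the compared groups, where fewer libraries leave fewer degrees of freedom, limma gave 23 and 2 in AD against Ngn2, 0 and 0 in AD against AM (2149 genes at an unadjusted p under 0.05), and 8 and 0 in AM against Ngn2 (3338). The GC correction gave 156, 241 and 401 higher in the first, second and last comparisons. The SNORA109 term gave 29 and 13, 50 and 20, 0 and 0 (1612 at an unadjusted p under 0.05 by limma), and 6 and 1. Quality weights gave 289 and 250 in AD against Ngn2, 109 lower in AD against AM, and 449 and 380 in AM against Ngn2. Leaving out 1 AD library at a time gave 10 to 52 and 6 to 18, 47 to 119 and 19 to 51, 7 to 38 and 16 to 45, and 184 to 288 and 97 to 187. Leaving out an AM or Ngn2 library leaves 1 in that group, which is assumed to vary like the others. Fewer libraries leave fewer degrees of freedom, and the filter then drops some genes. In all these settings, the called genes that were still tested kept their direction. The counts thus depend on which libraries are included, and the part of each of these reasons was not tested. Of 17 list calls, 0 held with an estimated correlation.

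With the replicate number as a block, limma called 0 higher and 0 lower in each of the 4 comparisons. There 1743, 1919, 1482 and 1334 genes had an unadjusted p under 0.05 by limma, and list calls fell to 10. AD 3 and the unnumbered AM library each had a block to themselves, so both are fitted exactly and 1 residual degree of freedom remains. Few calls can pass in that fit, so the 0 calls do not show an effect of pairing. Same-numbered libraries did not deviate together (correlations -0.0241, -0.0372, -0.0171 and 0.0228), and the labels do not say that numbers pair samples. With the unnumbered AM library numbered 3 in the block, counts were 18 and 6, 46 and 6, 1 and 5, and 44 and 5. Removal of mitochondrially encoded genes was not run because 0 such symbols were among those analysed here, and only the compared groups gives no separate fit for the first comparison. Depth is unknown, so its effect on low genes was not assessed.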

Other observations

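The tests of this part were chosen after the results they measure had been seen. The genes of the next paragraph come from the named genes of the report or were chosen after their values were seen.

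HEPACAM2 stood at 1124 and 1121 TPM in AM and at 52.0, 103 and 252 in AD. CGA, CALCA, TPH1 and SLC18A1 were also higher in AM than in Ngn2 by limma. EPCAM was at 368 and 586 TPM in AM, 368, 466 and 502 in AD, and 10.7 and 46.0 in Ngn2. MBP, best known from myelin, was 188 ± 31.7 TPM in AM (SD, n = 2), 145 ± 40.2 in AD (SD, n = 3) and 30.3 ± 0.792 in Ngn2 (SD, n = 2). PVALB, a marker of a class of interneurons, was above 0 in Ngn2 libraries alone, at 35.3 and 52.3 TPM.

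The 119 genes called between AD and the mean of Ngn2 and AM were set against other splits of the 7 libraries. Of 100 splits drawn from 105, 1 gave as many genes, the real one, and the highest other count was 11. Random assignment of all 7 libraries to groups is therefore unlikely to give this count, at 1 of 100 splits. That speaks for the groups together and not for AD alone. The splits that keep the 3 AD libraries together but mix Ngn2 with AM gave 4 and 5, so the count also rests on the separation of Ngn2 from AM, which the other splits place in the residual spread.

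Of 17 GABAergic identity genes, 7 were higher in AM than in Ngn2, and the list call is lost with an estimated correlation (adjusted p = 0.123). A wrong label could place an AM library closer to another group, but the AM libraries correlated at 0.862 with each other and at most 0.825 with any other library. RNA of AD neurons in the AM libraries cannot be the whole cause for MEIS2, whose lowest AM library stood at 232% of its highest AD library. Of the other 6 genes, GAD1 needs an AD share of at least 9.19%, DLX6-AS1 12.1%, DLX1 14.6%, GAD2 15.3%, DLX5 34.8% and DLX6 41.6%. GAD1 itself allows at most 12.7%, which argues against such RNA as the whole cause for DLX5 and DLX6. DLX1 and GAD2 need only slightly more than GAD1 allows, and GAD2 differed between the AM libraries (11.2 and 58.0 TPM). GAD1 is also the gene of this list with the lowest need, so DLX1 and GAD2 stay undecided. The lowest of 4012 abundant AD genes allow less: TAC3 0%, SERTM1 1.4%, MAP7D2 2.22%, UBE2L6 5.26% and SEMA3E 5.42%. They were picked on the same AM values, where a low value can be a failed estimate, so they decide nothing for GAD1, DLX6-AS1, DLX1 and GAD2. Other forms of this test, all tried after values were seen, were less clear: 4 of 4012 genes with a mean of at least 50 TPM in AD and at least 20 in each AD library lay below 25% of the level that the GAD1 share of 10.7% would need, where the rule asked for 5, and of 58 with at least 10 times the Ngn2 mean, 2 did and 12 lay above every AD library in AM. SNORA109 (12702 and 18997 TPM in AM, 0 and 0 in Ngn2) puts the AM and Ngn2 libraries wholly on opposite sides. A term for it left 6 genes higher and 1 lower in AM than in Ngn2, against 251 and 165, while the list kept its call with the preset correlation. That term is estimated from AD 3 against AD 1 and AD 2 alone, so it cannot decide whether the split made the calls. A library difference on that split and a smaller share of AD RNA stay open. RNA quality (MALAT1 and GAPDH, next paragraph) and the difference in factors stay open as untested.

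Of 20 neuronal maturation genes, 4 were lower in AM than in Ngn2, with a list median of -1.24 against -0.23 for all genes, and the list call is lost with an estimated correlation (adjusted p = 0.123). GC bias of the libraries may move the list, since fold changes and GC content correlated at Spearman's rho -0.174 across genes. With the preset correlation, the list had an adjusted p of 1.0e-04 after the GC correction, which argues against GC content as the whole cause of that call. A shift of all genes cannot be judged by the list test, which compares with other genes: its adjusted p after median centring, 9.6e-05, decides nothing. The SNORA109 split stays open, since its term is estimated from AD 3 against AD 1 and AD 2 alone and cannot decide it. MALAT1 (29350 and 38362 TPM in AM, 11015 and 13239 in Ngn2) and GAPDH (563 and 372 against 1035 and 716) move with the groups. A difference in RNA quality, for which they may stand, and the difference in factors stay open as untested.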
